A study of Mus musculus with 8 samples.

How the data were processed

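The study profiled RNA bound by ALKBH5 with eCLIP in nuclei of mouse embryonic stem cells, with an immunoprecipitate and an input in 2 replicates for wild-type cells with full-length ALKBH5 and for cells with ALKBH5 lacking its C-terminal disordered region. Per the labels' protocols the cells were crosslinked with UV light and the nuclei isolated before library construction. Per the submitters' processing notes cutadapt, STAR, UMI-tools and MACS2 were used with the build GRCm39, and versions, settings and the role of each tool are not given in the sources used here. Each immunoprecipitate had a list of peaks of its own, so peaks had been called per replicate. The inputs were not analysed here as separate data, and whether they served as the control in peak calling is not given in the sources used here. Without such a control, peaks can follow RNA abundance as well as binding. The lists named for the wild type were taken as full-length, and the other lists, named for a knock-in, as del-cIDR, since this was the only other genotype.

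For each peak the authors deposited a position, a fold enrichment (a ratio over the background of the peak caller), a −log10 p-value, a −log10 q-value and a score. The deposited summit column is a distance in bases from the peak start, of a kind other than these units. The lowest deposited −log10 q was 1.31 to 1.34 over the 4 lists, which places the authors' q limit near 0.05. The smallest deposited peak width was 297 and 243 bp in the full-length and 300.0 and 301 bp in the del-cIDR replicates, so a minimum length had been set per library. No peak carried a strand, so RNA from opposite strands could not be separated. Read numbers are unknown, and a longer or wider list can follow from more reads as well as from more binding. Confidence intervals below cover counting of peaks only.

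All deposited peaks were used. Peak numbers, covered length and widths were compared between genotypes as mean and SD of 2 replicates, with a two-sided exact permutation test whose smallest possible p is 0.333. Wide peaks were set at 2 kb after the lists were seen. Lists were compared by the Jaccard index of covered bases and by the percent of peaks overlapped by at least 1 bp over all 6 pairs, beside lists shifted by 10 kb and 1 Mb in both directions. For regions, peaks of the 4 libraries were merged where they overlapped, and each region was classed by the libraries with a peak there. Del-cIDR-only and full-length-only counts were compared with a two-sided exact binomial test. Peaks were ranked within their own list by −log10 q. Shares over peaks have exact (Clopper-Pearson) 95% intervals.

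Regional peak numbers were tested with limma (lmFit, and eBayes with trend) on log2 of summits per 10000 summits of the library plus a pseudocount of 0.5. Windows of 1 Mb with 4 or more summits over the 4 libraries entered, on the numbered, X and Y chromosomes, with Benjamini-Hochberg adjustment. Fold changes on this scale understate the change of windows with few peaks. The plan was to run this test on genes. The annotation used here as a name table is on an older build, GRCm38.p6, and was not mixed with these positions, so windows took the place of genes, as was decided after the lists were seen. For the same reason gene-level sets, transcript features, distances to transcription start sites, sequence at summits and the 19 gene lists fixed beforehand were not analysed here. The test was tested on simulated data for the 2267 windows, with no dispersion beyond counting noise since none was estimated from the replicates. It recovered 11% of 100 windows changed 2-fold and 39% of 100 windows changed 4-fold, with 1 false call among 2067 unchanged windows. Many changed windows thus went uncalled in that simulation. The share missed in the data may differ, since the estimate of dispersion could not be negative and replicates may vary less than counting noise. Fewer windows were also changed than the 1021 that had an unadjusted p under 0.05 in the data. The counting of regions was also tested on simulated lists.

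Named regions followed a rule set before the data were examined, adapted from genes to regions and changed for the genotype-only sets. For those sets the plan took the genes with the most summits and used rank by −log10 q only for ties. The rule as run took the 10 regions of each genotype-only set with the best mean rank by −log10 q. It also took the 5 best ranked regions of all 4 libraries and the 10 windows per direction with the smallest adjusted p. Parts of the rule that needed genes were not run. Alternatives planned before the data were examined were a −log10 q of at least 5, a fold enrichment of at least 4 for lists and regions, the same number of peaks from each list (16636, by rank), each replicate left out, 50% overlap, merging of peaks within 100 bp, pseudocounts of 0.25 and 2, windows with at least 1 or 8 summits, no scaling and a replicate block. Those added later were windows of 500 kb and 2 Mb, joining of peaks within 5 kb, centring on the median window, 4-fold enrichment for windows, other widths for wide peaks, and leaving out mitochondrial and scaffold peaks. Software was Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.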

Results

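RNA binding of ALKBH5, an enzyme that removes the N6-methyladenosine mark from RNA, was profiled by eCLIP, in which UV light crosslinks proteins to the RNA they touch before immunoprecipitation. The cells were E14TG2a mouse embryonic stem cells, a line kept in the pluripotent state, and the RNA came from their nuclei. Wild-type cells with the full-length protein were compared with cells whose endogenous ALKBH5 lacks its C-terminal intrinsically disordered region, called del-cIDR here. The series title frames the question as whether disordered regions restrain where demethylases go. The 8 samples were an immunoprecipitate and an input in 2 replicates for each genotype, and the peak lists of the 4 immunoprecipitates were analysed here. The labels do not say whether replicates came from separate cultures, so the p-values below measure only the spread between these samples. The number of reads behind each list is unknown. Positions are in GRCm39.

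Both forms of ALKBH5 gave lists of similar length, but the full-length lists held many broad peaks that the del-cIDR lists lacked. The full-length lists held 19892 and 16636 peaks and the del-cIDR lists 17584 and 18841. The means were 18264 ± 2302 and 18212.5 ± 889 (SD, n = 2 per genotype), a difference of -51.5 peaks that lay within the replicate spread (two-sided exact permutation p = 1). Peaks of 2 kb or wider numbered 825 and 361 in the full-length lists, against 16 and 26 in the del-cIDR lists. These counts averaged 593 ± 328 and 21.0 ± 7.07 (SD, n = 2 per genotype), a 28.2-fold difference with no overlap between genotypes. No two-sided exact permutation p under 0.333 is possible with 2 replicates each, and this difference reached it. Wide peaks made up 19.9% ± 4.19 of the covered length in full-length lists and 0.675% ± 0.189 in del-cIDR lists (SD, n = 2). Peaks of 5 kb or wider averaged 77.5 ± 33.2 in the full-length lists (SD, n = 2), and none was listed for del-cIDR.

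**Figure D1:**
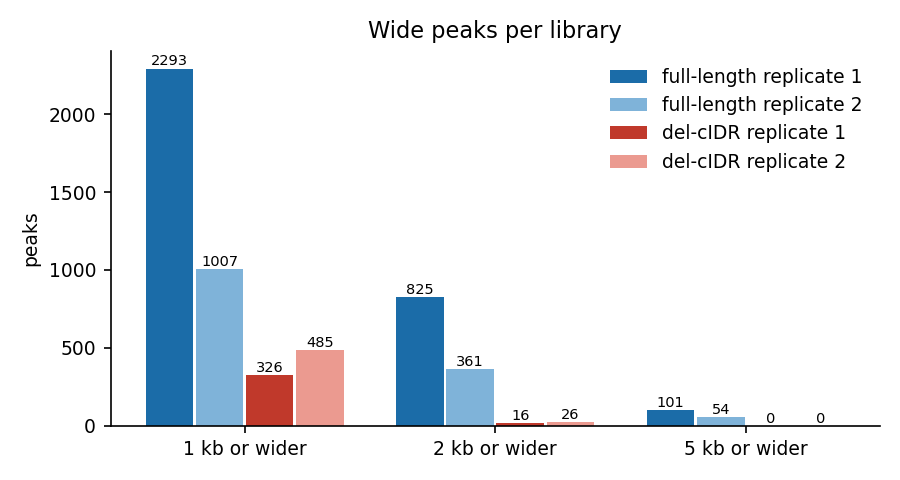
Number of peaks (vertical axis) at or above 3 widths (horizontal axis) in each of the 4 libraries, 1 bar per library. The full-length libraries hold 825 and 361 peaks of 2 kb or wider, and the del-cIDR libraries 16 and 26.

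The widest full-length peak spanned chromosome 2 from 76566146 to 76585288 in replicate 1, a width of 19143 bp, and had nearly the same ends in replicate 2, where it measured 19070 bp. The next widest in both replicates lay on chromosome 14, from 61440189 to 61453163 in replicate 1 and 12975 bp wide. Neither region held a peak in a del-cIDR list. A wide full-length peak on chromosome 19, from 8984997 to 8996800 in replicate 1, did overlap peaks in all 4 libraries. The widest del-cIDR peaks were 3319 bp, on chromosome 19 from 5892075 to 5895393 in replicate 1, and 3776 bp, on chromosome 12 from 109688745 to 109692520 in replicate 2. Of the wide full-length peaks, 99.5% of those of replicate 1 and 100% of those of replicate 2 overlapped a peak of any width in the other replicate, and 42.3% and 99.2% overlapped a wide one. A peak in at least 1 del-cIDR list was found at 22.2% and 28.0% of them, and peaks in both del-cIDR lists at 8.85% and 11.4% (exact 95% binomial intervals 6.9998 to 11.0% and 8.27 to 15.1% over peaks). The median width over all peaks was 335 ± 62.2 bp in full-length and 328 ± 4.24 bp in del-cIDR lists (SD, n = 2), a difference whose sign depended on which full-length replicate was kept. Peaks at the minimum width of their library made up 14.8% ± 3.29 of the full-length and 27.5% ± 1.12 of the del-cIDR lists (SD, two-sided exact permutation p = 0.333, n = 2 per genotype). The covered length was 9.97 ± 3.31 Mb and 7.49 ± 0.565 Mb (two-sided exact permutation p = 0.667, n = 2 per genotype).

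Over 50% of the peaks of each list overlapped a peak of the other replicate, and far fewer overlapped a peak of the other genotype. The Jaccard index of covered bases was 0.461 between the full-length replicates and 0.404 between the del-cIDR replicates. Across genotypes it ranged from 0.0606 to 0.0730 over the 4 pairs. Within a genotype 54.0 to 76.2% of the peaks of a list overlapped a peak of the other replicate by at least 1 bp, against 15.9 to 21.9% across genotypes. The overlap across genotypes was above the level of displaced lists, since shifting a list by 10 kb left 2.85 to 3.22% of its peaks overlapping and shifting it by 1 Mb left 0.869 to 1.13%. All 4 pairs across genotypes were lower than both pairs within genotypes, and this was described and not tested.

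**Figure D2:**
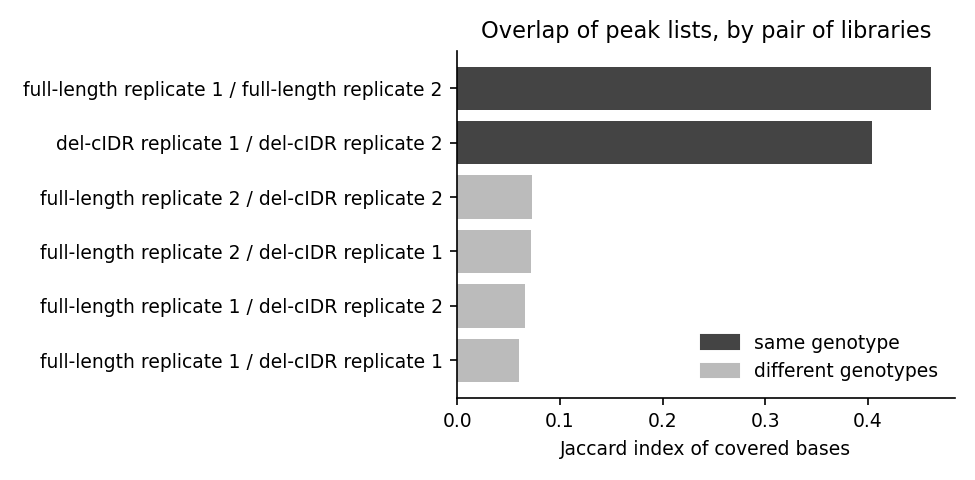
Jaccard index of covered bases (horizontal axis) for the 6 pairs of libraries (vertical axis), with dark bars for replicates of a genotype and light bars for pairs across genotypes. The pairs within a genotype stand at 0.404 and 0.461, and the pairs across genotypes lie between 0.0606 and 0.0730.

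Merging the 4 lists gave 43029 regions, and most regions found in both replicates of a genotype were missing from the other genotype. Both full-length replicates and neither del-cIDR replicate held a peak at 7549 regions, and the reverse held at 7609. Another 2022 regions held a peak in all 4 libraries, and 22700 regions (52.8%) in a single library. Of the regions in both full-length lists, 71.8% had no del-cIDR peak, and of those in both del-cIDR lists, 69.3% had no full-length peak. Regions found in exactly 1 library of each genotype numbered 336 and 527 in the 2 crossed pairings of the libraries. The sum of both genotype-specific sets, 15158, was 28.8 times the larger of these. That ratio is not an excess over the level without a genotype effect. Any difference shared by the libraries of a genotype lowers the crossed counts while it raises the genotype-specific ones. The regions divided about evenly by direction, since 50.2% of the genotype-specific regions were del-cIDR regions (exact 95% binomial interval 49.40 to 50.997%, two-sided exact binomial p = 0.632). That test compares these libraries, not the conditions. The balance depended on the peaks kept: with only peaks of at least 4-fold enrichment the del-cIDR share was 39.4%, with 3624 full-length and 2361 del-cIDR regions (exact binomial p = 2.94e-60).

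**Figure D3:**
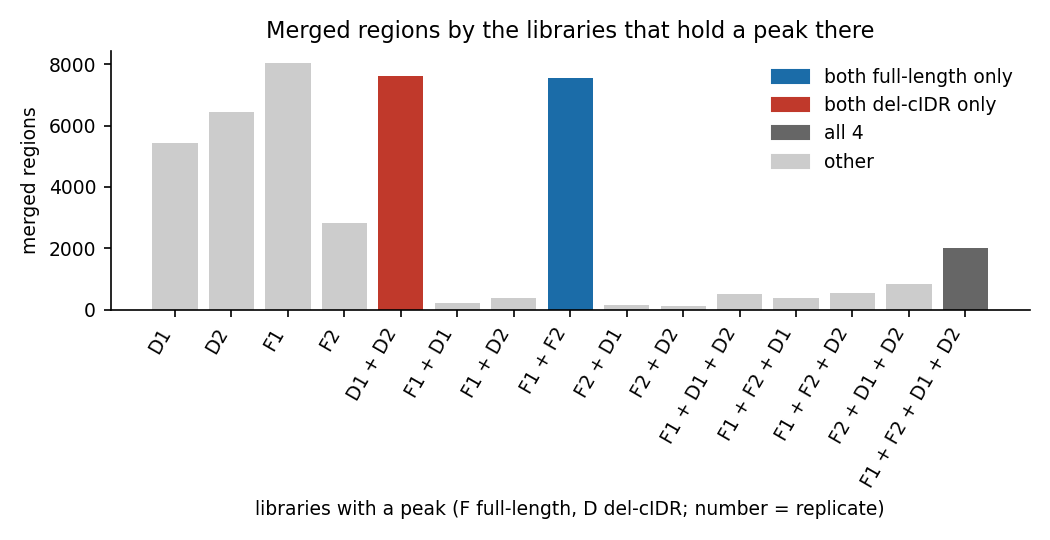
Number of merged regions (vertical axis) for each combination of libraries that held a peak there (horizontal axis, F for full-length and D for del-cIDR). The bars for both full-length only (7549 regions) and both del-cIDR only (7609 regions) stand far above the crossed pairs, and 2022 regions were in all 4 libraries.

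Full-length-only regions were broader than del-cIDR-only regions, where a region joins the overlapping peaks of both replicates. Single peaks did not all follow this. Their median width was 379 and 291 bp in the full-length replicates and 325 and 331 bp in the del-cIDR replicates, so full-length replicate 2 lay below both. The median width was 543 bp for the full-length-only set (quartiles 370 and 956 bp), 420 bp for the del-cIDR-only set (quartiles 301 and 628 bp) and 304 bp for regions in all 4 libraries. Regions of 2 kb or wider made up 8.84% of the full-length-only set, 667 regions, and 0.421% of the del-cIDR-only set, 32 regions. The fold enrichments given next are the authors' own values for each peak and serve to describe peaks within a list. The full-length-only region with the best mean rank by −log10 q lay on chromosome 19 from 8979069 to 8984821, with 39.5-fold and 27.0-fold enrichment and ranks 5 and 18 in the 2 replicates. It ended shortly before the wide full-length peak from 8984997 to 8996800, whose region held a peak in all 4 libraries. This region is thus not a site apart from those that del-cIDR shares. The region next in order, on chromosome 4 from 145430388 to 145431095, had 24.4-fold and 18.6-fold enrichment. Regions on chromosome 3 from 133169265 to 133173928 and on chromosome 10 from 62673675 to 62676148 followed. Chromosome 1 gave a close pair, from 34238421 to 34238927 and from 34266863 to 34268613. The region on chromosome 2 from 76607926 to 76609910 had the highest enrichment of the 10, 49.3-fold and 36.1-fold. The others among the 10 lay on chromosome 4 from 145263262 to 145266814 and from 147143936 to 147144856, and on chromosome 5 from 125462795 to 125463547. All 10 held a peak in both full-length replicates with enrichment of 7.26-fold or more, and 4 of them were at least 2 kb wide.

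The leading del-cIDR-only regions were mostly narrow, and 1 of the 10 was at least 2 kb wide. The best by mean rank were on chromosome 19 from 4128024 to 4128326, with 2.43-fold and 3.55-fold enrichment, and on chromosome 8 from 52789740 to 52790048, with 2.94-fold and 5.22-fold. Chromosome 19 gave a close pair from 5845869 to 5848348 and from 5848484 to 5848882, with 3.01-fold and 3.31-fold in the first and 1.86-fold and 2.14-fold in the second. The region on chromosome 13 from 68419153 to 68419460 had the highest enrichment of the 10, 24.6-fold and 21.4-fold. Enrichment of 7.85-fold and 12.7-fold was given for chromosome 1 from 157906229 to 157906532, of 6.43-fold and 12.2-fold for chromosome 1 from 44237886 to 44238190, and of 12.5-fold and 10.4-fold for chromosome 9 from 28855670 to 28855970. The remaining members were on chromosome 15 from 80923882 to 80924184 and on the mitochondrial chromosome from 4819 to 5125. In 6 of these 10 regions, 1 or both del-cIDR peaks fell under 4-fold enrichment, so the region was lost when such peaks were left out.

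Regions in all 4 libraries were led by short, strongly enriched sites. The first, on chromosome 10 from 115700831 to 115701139, ranked 1 in both del-cIDR lists and 11 and 3 in the full-length lists. Its fold enrichment was 888 and 315 in del-cIDR and 85.1 and 113 in full-length replicates. The region on chromosome 6 from 96569949 to 96570255 ranked 3 in both del-cIDR lists, and that on chromosome 2 from 129158421 to 129158723 ranked 2 in both. The other members were on chromosome 2 from 44427981 to 44428284 and on the mitochondrial chromosome from 195 to 1171, the latter at no more than 3.11-fold enrichment in any library.

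The highest ranked del-cIDR peaks mostly lay in regions of all 4 libraries, and the highest ranked full-length peaks did so less often. Among the 500 highest ranked peaks, 77.8% and 78.8% in the del-cIDR replicates lay in regions of all 4 libraries, against 23.0% and 40.8% in the full-length replicates. The median width of these peaks was 301 and 302 bp in del-cIDR, close to the minimum of those lists, and 758.5 and 383 bp in full-length replicates. Peaks in both lists of their own genotype and in neither of the other made up 12.8% and 11.6% of that bin in del-cIDR and 65.4% and 46.8% in full-length replicates. The exact 95% binomial intervals over peaks did not overlap between genotypes, with 10.0 to 16.0% as the higher del-cIDR interval and 42.4 to 51.3% as the lower full-length interval. The intervals of the 2 full-length replicates did not overlap each other either (61.0 to 69.6% and 42.4 to 51.3%), so such intervals do not measure the replicate spread. From rank 2001 to 5000 the 4 lists came together at 57.5 to 59.8% own-genotype peaks. These shares describe ranks within each list, which show no change between lists of different lengths, and were not tested between genotypes.

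**Figure D4:**
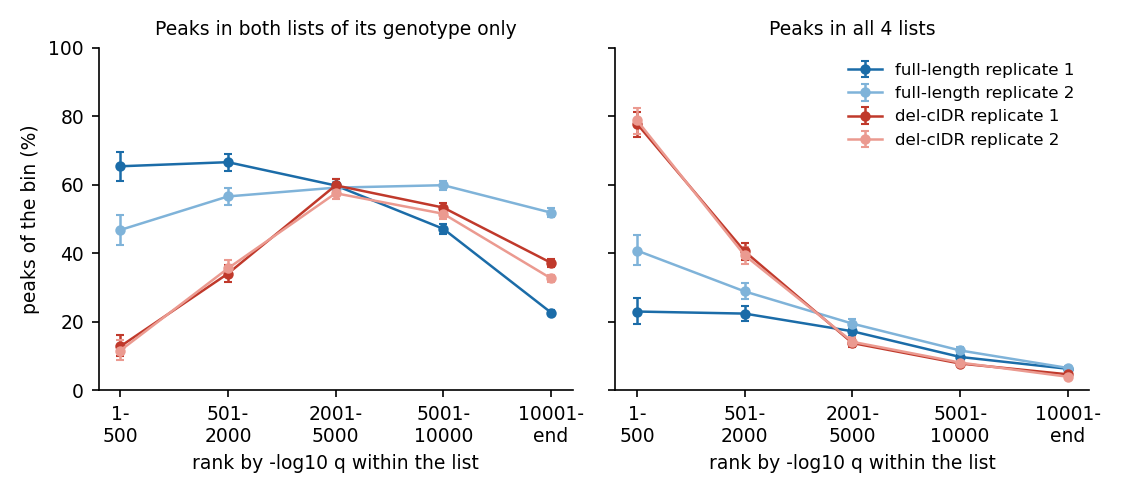
Percent of peaks (vertical axis) that lie in both lists of their own genotype only (left) or in all 4 lists (right), by rank within the list (horizontal axis), with exact 95% binomial intervals over peaks as error bars. In the top 500, del-cIDR libraries have 77.8% and 78.8% in all 4 lists and full-length libraries 23.0% and 40.8%.

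Peak numbers per window were correlated between genotypes (Spearman 0.612 to 0.641), though less than between the full-length (0.888) or del-cIDR replicates (0.915). Within this shared distribution, some parts of chromosomes held far more peaks of 1 genotype. Full-length peaks crowded into chromosome 4 between 144 and 148 Mb, where the full-length replicates had 324 and 344 peaks and the del-cIDR replicates 34 and 37. A further cluster on chromosome 2 between 174 and 178 Mb held 241 and 184 full-length against 21 and 21 del-cIDR peaks. Chromosome 13 between 64 and 68 Mb held 174 and 143 against 34 and 26. In the other direction, 7 adjoining windows on chromosome 11 between 96 and 103 Mb held 236 and 248 del-cIDR against 96 and 80 full-length peaks. Runs of 4 windows held 128 and 158 against 74 and 62 on chromosome 17 between 25 and 29 Mb, 141 and 140 against 62 and 56 on the same chromosome between 34 and 38 Mb, and 98 and 110 against 42 and 40 on chromosome 11 between 67 and 71 Mb. Full-length runs of 4 windows on chromosomes 5, 8 and 12 held 3.77, 4.02 and 4.46 times as many full-length as del-cIDR peaks. These runs, all those of at least 4 windows, were picked after the window results were seen.

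**Figure D5:**
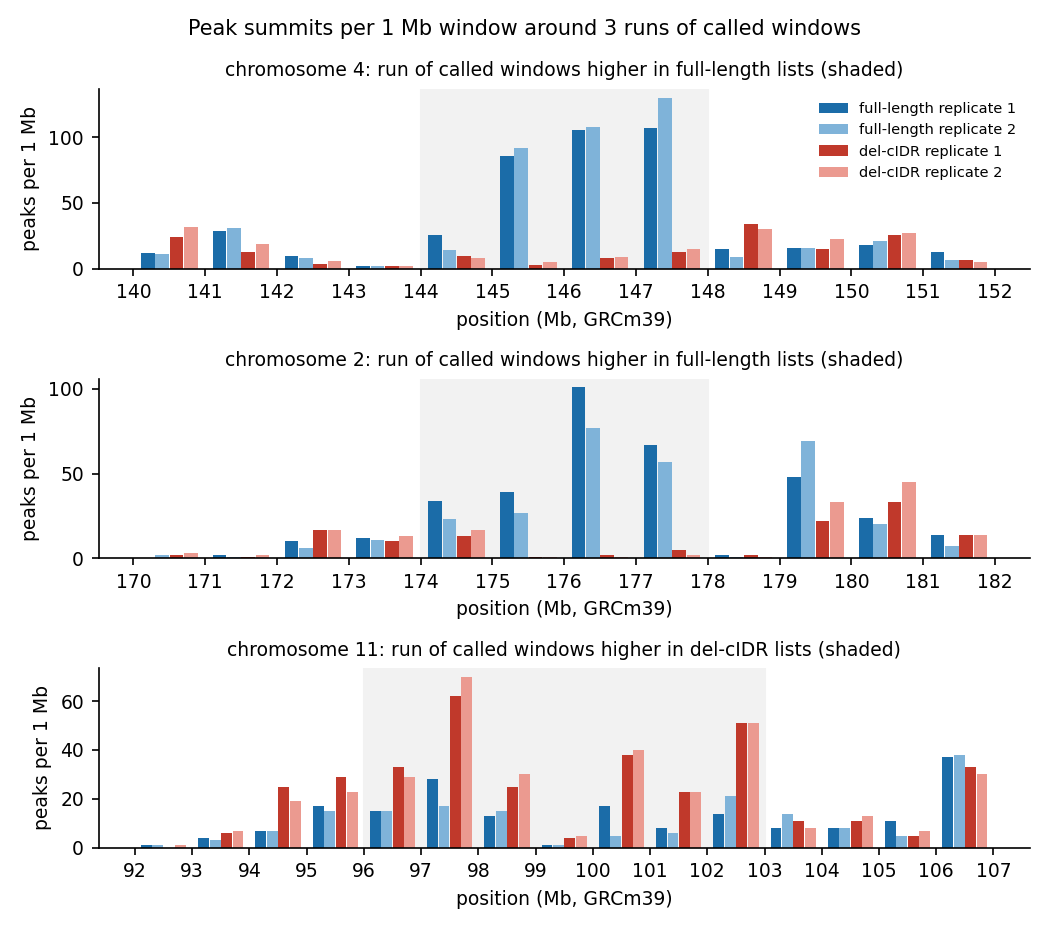
Peak summits per 1 Mb window (vertical axis) along 3 chromosome segments (horizontal axis, Mb in GRCm39), 1 bar per library, with the run of windows past the test shaded. Full-length bars reach 105 and 108 at 146 Mb on chromosome 4, where del-cIDR bars stand at 8 and 9, and del-cIDR bars exceed full-length bars across 96 to 103 Mb of chromosome 11.

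Over 2267 windows of 1 Mb, limma called 323 with more full-length and 404 with more del-cIDR peaks (Benjamini-Hochberg adjusted p under 0.05), and 1021 windows had an unadjusted p under 0.05. The windows called for full-length held 34.6% of full-length and 9.22% of del-cIDR peaks of the tested windows, and those called for del-cIDR held 12.3% and 34.1%. The median window was 0.20 higher in del-cIDR on the log2 scale, and the log2 values below are given relative to it unless stated otherwise. The SE and adjusted p printed with them belong to the difference before this subtraction, which is what limma tested. With each library centred on its median window the calls numbered 334 and 279, so which direction had more calls depended on the centring. Fits without del-cIDR replicate 1 gave 161 and 117 calls and fits without del-cIDR replicate 2 gave 168 and 105, with the lone replicate assumed to vary like the other genotype. Calls also fell to 180 and 230 with lists of the same length, 161 and 233 without scaling, 160 and 189 with only peaks of at least 4-fold enrichment, and 100 and 100 with peaks within 5 kb joined.

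The windows with the smallest adjusted p for full-length included all of chromosome 4 from 145 to 148 Mb. From 146 to 147 Mb the replicates had 105 and 108 full-length against 8 and 9 del-cIDR peaks, a log2 difference of 3.72 ± 0.18 (SE, limma adjusted p = 0.00120). The window from 145 to 146 Mb had 86 and 92 against 3 and 5 peaks, and that from 147 to 148 Mb 107 and 130 against 13 and 15. On chromosome 2 the window from 176 to 177 Mb held 178 full-length peaks over both replicates against 3 del-cIDR peaks, a ratio of 59.3 with an exact 95% counting interval of 19.98 to 290. The window from 175 to 176 Mb held 39 and 27 against 1 and 1, as did that of chromosome 1 from 139 to 140 Mb with 39 and 25 against 1 and 1. On chromosome 8 from 45 to 46 Mb there were 27 and 28 full-length peaks and none was listed for del-cIDR. Chromosome 15 from 35 to 36 Mb held 78 and 52 against 5 and 5, and chromosome 13 from 62 to 63 Mb held 84 and 84 against 7 and 5. The window of chromosome 4 from 123 to 124 Mb, with 194 against 23 peaks over both replicates, lost its call when peaks within 5 kb were joined. Its log2 difference went from -2.98 to -0.76 before the median window is subtracted (limma adjusted p = 0.0759, the highest over all alternatives). The lowest limma adjusted p, 6.17e-51, came with the replicate block. That fit leaves little replicate spread to estimate, so its p does not measure the spread of 2 replicates. Joining peaks within 5 kb also reduced the differences of the other windows of this paragraph, though these kept their calls. Before the median window is subtracted, chromosome 2 from 176 Mb went from -5.24 to -3.44 and chromosome 15 from 35 Mb from -3.45 to -3.33. The counting interval above treats each peak as a separate event.

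The leading del-cIDR windows had smaller differences on the log2 scale, which understates windows with few peaks. By peak ratio not all were smaller, as chromosome 5 from 117 Mb (11.3) exceeded the full-length window of chromosome 4 from 123 Mb (8.43). Chromosome 1 from 171 to 172 Mb held 29 and 31 del-cIDR against 4 and 3 full-length peaks, a log2 difference of 2.62 ± 0.23 (SE, limma adjusted p = 0.00220). Chromosome 5 from 134 to 135 Mb held 25 and 32 against 4 and 3, and from 117 to 118 Mb 15 and 19 against 2 and 1. Chromosome 11 gave windows from 51 to 52 Mb, with 21 and 22 against 3 and 3 peaks, and from 115 to 116 Mb, with 58 and 48 against 13 and 8. Chromosome 19 from 6 to 7 Mb held 45 and 58 against 13 and 13, a log2 difference of 1.70 ± 0.20 (SE, limma adjusted p = 0.00328). Chromosome 10 from 117 to 118 Mb held 20 and 26 against 3 and 3, and chromosome 15 from 78 to 79 Mb 27 and 23 against 5 and 4. No full-length peak was listed on chromosome X from 52 to 53 Mb, where del-cIDR replicates had 6 and 6, or on chromosome 18 from 57 to 58 Mb, where they had 5 and 5. Of these 10 windows, 5 kept their call under every alternative in which they were tested, and that of chromosome 18 was not tested among peaks of at least 4-fold enrichment. With only such peaks the other 5 lost their call. On the log2 scale before the median window is subtracted, the differences fell from 2.93 to 1.62 on chromosome 5 from 117 Mb, from 2.26 to 1.503 on chromosome 15 and from 2.52 to 1.35 on chromosome 11 from 51 Mb. They did not fall on chromosome 5 from 134 Mb (2.74 and 2.90) and chromosome 10 (2.60 and 2.91), where the adjusted p rose above 0.05 all the same. The window from 51 Mb of chromosome 11 also lost its call with the same number of peaks from each list, at a larger difference of 2.905 (limma adjusted p = 0.0563). Over all alternatives its limma adjusted p ranged from 3.44e-11, again with the replicate block, to 0.0750.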

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

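In this part, the tests of the peak threshold, of the fragment length and of sequencing depth were chosen after the result was seen, and the joining of neighbouring peaks was added later. Peaks on unplaced scaffolds entered the list and region counts but not the window test, and no comparison above looked at them on their own. There, 1 scaffold held a mean of 5 peaks in the full-length lists (5 and 5) and 0 in the del-cIDR lists. Another held a mean of 12.5 peaks in the del-cIDR lists (13 and 12) against 4 in the full-length lists (5 and 3).

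Regions specific to a genotype outnumbered crossed regions, and peaks near the calling threshold, which come and go by chance, are a candidate explanation. Among the 2000 highest ranked peaks, those without a peak in the other genotype exceeded those without a peak in the other replicate by at least 28.2 percentage points in every list, and by 65.8 points in full-length replicate 1. Among the 500 highest ranked, 14.0% and 12.2% of del-cIDR peaks lacked a peak in the other genotype, against 1.8% and 0.6% in the other replicate. In full-length lists these were 65.6% and 48.4% against 0.6% and 3.6%. Peaks far above the threshold thus differed between genotypes too, less so at the top of the del-cIDR lists, which argues against the threshold as the whole cause. The deletion itself remains open, as does any difference in preparation that the genotypes' libraries shared, since no label gives a batch.

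Wide peaks appeared in the full-length lists, and a longer fragment length in peak calling could widen peaks. Full-length replicate 2 had the shortest minimum width, 243 bp, and still held 361 peaks of 2 kb or wider against 16 and 26 in the del-cIDR lists, which argues against that cause. Deeper sequencing could join sites that remain separate narrow peaks in shallower libraries. At most 11.4% of wide peaks in a full-length list held a peak in both del-cIDR lists, but a shallower library would lose such sites as well, and read numbers are unknown, so depth and genotype cannot be told apart here. Broad coverage of certain RNAs by the full-length protein, and a different level of those RNAs between the cell lines, also remain open and untested.

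Windows with more full-length peaks may partly reflect a broad signal split into several peaks. Joining peaks within 5 kb left 54.2% and 53.2% of the peaks of the full-length lists and 70.3% and 67.8% of those of the del-cIDR lists, and 29.1% of the 323 full-length windows were then called again, with 301 of the 323 keeping their direction. Relative to the median window of each fit, the median log2 difference of these windows moved from -1.81 to -1.19 (quartiles -2.26 and -1.41 before, -1.79 and -0.72 after). Of the 229 lost calls, 168 had moved by at least their SE, turned or left the test, while 67 would have passed at the unadjusted limit that Benjamini-Hochberg adjustment set before joining (0.0160, against 0.00440 after), so the adjustment ended part of the calls. Of the 404 del-cIDR windows 93 (23.0%) were called again, with a median relative log2 difference of 1.33 before and 1.00 after. That was a smaller move than in the full-length windows on the relative scale only. Before the median window is subtracted, the medians went from -1.61 to -1.11 in full-length and from 1.53 to 1.08 in del-cIDR windows, which is a similar move. How much of the full-length pattern comes from splitting stays open.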

How the results depend on the processing

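The windows of other sizes, joined or centred peaks, 4-fold windows, other widths and the lists without mitochondrial and scaffold peaks were chosen after seeing the data. Of the values that sum up a comparison, 84 stayed within the replicate SD, within 1.5 times a count or on the same side of a test, 26 moved further, 5 turned past the threshold and 4 passed it in the same direction. Part of the 84 was fixed in advance and shows no robustness. For peak number, covered length, median width and wide peaks, leaving out 1 of 2 replicates cannot move the difference beyond that SD. For peak number, lists of the same length and the replicate block also have a fixed outcome. Within that SD some still turned: with a replicate left out, del-cIDR minus full-length was -1679.5 to 1576.5 peaks, -51 to 37 bp in median width, -4.82 to -0.144 Mb in covered length and -804 to -340 wide peaks. With only peaks of 4-fold enrichment, del-cIDR minus full-length peaks was -2391.5, full-length-only, del-cIDR-only, crossed and all-library regions numbered 3624, 2361, 193 and 662, and windows 160 and 189 (full-length, then del-cIDR). The del-cIDR share of genotype-specific regions moved from 50.2% under several settings: 48.7% with −log10 q of at least 5, 48.8% with lists of the same length, 39.4% with 4-fold enrichment, 52.0% with 50% coverage of the region, 51.02% with merging within 100 bp, and 34.9 to 64.2% with a replicate left out. The last follows from construction, since a genotype with 1 list has no replicate filter; full-length-only regions then ranged from 7950 to 15779 and del-cIDR-only regions from 8128 to 14268. Within minus between Jaccard ranged from 0.331 to 0.395 with a replicate left out, and the overlap difference was 35.4 points with reciprocal 50% overlap against 44.5. Wide peaks differed by -1244.5 at 1 kb and -77.5 at 5 kb, by construction of the width. Windows numbered 180 and 230 with lists of the same length, 161 and 233 without scaling, 100 and 100 with joined peaks, and with a replicate left out 161 to 389 and 105 to 560; apart from joining, the cause was not tested. With a replicate block, 384 and 531 windows were called and the mean paired difference in peaks was -51.5 (-2308 and 2205). The difference of replicate 1 minus replicate 2 correlated at -0.00807 between genotypes over windows. That value cannot exclude a shared preparation, and the labels link the samples only by a replicate number. Of the values for named windows, 292 held and 7 lost their call, and for named regions 68 held and 7 moved. Alternatives that needed genes or sequence were not run. Unknown read depth limits what a missing peak shows.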

Other observations

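The comparisons of this part were all chosen after the lists were seen. Peaks were spread unevenly over chromosomes, and the genotypes differed in how. Chromosome 11 held 8.33% ± 0.135 of del-cIDR and 6.23% ± 0.121 of full-length peaks, and chromosome 19 held 3.23% ± 0.0953 and 2.30% ± 0.00342 (SD, n = 2 per genotype). Chromosomes 17 (5.73% ± 0.0700 against 4.48% ± 0.0667) and 10 (5.34% ± 0.155 against 4.35% ± 0.0976) were also higher in del-cIDR. Chromosome 13 went the other way, with 5.30% ± 0.0718 of full-length and 3.56% ± 0.228 of del-cIDR peaks, and so did chromosome 4, with 7.96% ± 0.426 and 6.15% ± 0.189. The replicates of the genotypes did not overlap on 17 of the 21 chromosomes, 7 higher in del-cIDR and 10 in full-length. For a single chromosome chance gives 33.3%. The shares of a library depend on each other and all come from the same libraries, so the 17 cannot be read as an excess over that level. A two-sided exact permutation test cannot go below p = 0.333 with these replicates, and no other test was run on the chromosome shares.

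Narrow peaks of high enrichment, by each list's own values, made up 9.34% and 8.82% of the del-cIDR lists and 1.24% and 2.51% of the full-length lists. Peaks within 10 bp of their library's minimum width and with at least 10-fold enrichment numbered 1642 and 1661 in the del-cIDR lists and 246 and 418 in the full-length lists. Of the del-cIDR ones, 48.8% and 47.6% lay in regions of all 4 libraries, and of the full-length ones, 70.3% and 80.9%. Regions with a peak in at least 1 list of the other genotype held 71.5% and 71.5% of the del-cIDR ones and 73.6% and 87.3% of the full-length ones. At 848 regions a peak was missing from full-length replicate 1 alone, and at 502 from full-length replicate 2 alone. The former were 301 bp in median width with a median enrichment of 7.47-fold and 7.49-fold in the del-cIDR replicates, and the latter 454.5 bp with 3.06-fold and 3.12-fold.

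Mitochondrial RNA carried peaks in each library, 6 and 7 in the full-length and 7 and 7 in the del-cIDR lists. The peak ranked 1 in both full-length lists lay there, from 1322 to 2257 in replicate 1 and from 1316 to 2203 in replicate 2. Del-cIDR replicate 1 had a peak from 1927 to 2260 at rank 257, and replicate 2 had none overlapping that stretch.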
